A study of Caenorhabditis elegans with 3 samples.

How the data were processed

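Messenger RNA of Caenorhabditis elegans was compared on 3 two-colour DNA microarrays. Per the labels, channel 2 of each array held RNA of adult hermaphrodites with embryos from a stage or sample named TP10, and channel 1 held a wild-type mixed reference. The labels do not spell out TP10 or say what was mixed in the reference. They number the 3 RNA samples as preparations 1 to 3, each after the words "adult w/ emb 1", and do not say what that 1 stands for. The preparations were taken as replicates of a single group. Nothing in the labels says that the preparations came from separate cultures. The p-values of single genes therefore measure the spread between these preparations, which may be partly technical. Each array carries its own date in the labels, so array, preparation and day cannot be separated.

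The deposited table gives the authors' log2 ratio of the 2 channels for 20000 array features. The scale was read from the values. On each array, 2 raised to the value was a whole number of thousandths (tolerance 0.01 thousandths) for at least 99.98% of values. The array medians were -0.00868, 0.0172 and 0.0101, so the ratios had already been centred, by a method not given in the sources used here. Background correction, spot filters and within-array normalization are likewise not given in the sources used here. No dye is named, so the direction of the ratio is not settled. It was read as TP10 over reference because the sample descriptions order the comparison that way and TP10 is the second channel. If the table were inverted, every "higher" would read "lower" and the sizes would stand. Spot intensities were not used here, so it is unknown which features were above background or saturated, and the number of arrays limits the precision.

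Feature names came from the platform annotation, in which 15655 features had 1 gene, 198 had several and 4147 were not listed. Of the 15655, 15569 matched a RefSeq gene of assembly WBcel235 by gene identifier, which gave current symbols and chromosomes. Coordinates from that assembly were not used because the build behind the array design is unknown. Features with several genes or none were tested but never named. A value on all 3 arrays was required, which kept 19748 features. Features of the same gene were averaged on the log2 scale; 429 genes had more than 1 feature, and in 6 of them the features differed by over 1 log2 unit. This gave 19300 genes and unnamed features, of which 15112 were single genes. Each array was then centred on its median.

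The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only, two-sided), with Benjamini-Hochberg adjustment over all 19300 and a threshold of 0.05. Values are given as mean ± SD with n = 3, and folds are 2 to the power of the absolute mean. The reference RNA has no replicates of its own in this test, and the labels name no array with exchanged dyes, so its own spread and any dye bias common to the arrays are not in the error. Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 19 lists with at least 5 measured genes. The test asks whether list members differ from the other genes. With the preset correlation its degrees of freedom are set by the number of genes and not by the 3 arrays. These list p-values therefore do not measure the spread between preparations. On the residual degrees of freedom of the arrays, the adjusted p of the germ line list went from 1.25e-16 to 0.0792. All list p-values in the text are adjusted in this way unless stated. Every list call was repeated with a correlation estimated from the data. That repeat takes its p on the 2 residual degrees of freedom of 3 arrays. On these, none of the 10 lists called with the preset correlation passed even with a correlation of 0 (camera, smallest adjusted p = 0.0524). Failures of the repeat could therefore not have come out otherwise, and they decide nothing about correlation within a list. A second test, fry, asks another question, namely whether the members of a list move one way against no change. Genes on the X chromosome were tested in the same way against genes of the other chromosomes.

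The tests, the 20 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. For lists, X-linked genes and named genes, centring on the mean and scaling to one spread, alone or with an estimated correlation, were chosen after seeing the data. The rule named the 8 genes with the highest and the 8 with the lowest mean among genes past the threshold with 1 sign on all 3 arrays. A gene needed a symbol that is not a bare sequence name. From each list the rule named the 3 largest changes past the threshold and, for yolk proteins, every measured member. Genes named outside the rule are marked as chosen after their values were seen, or as listed before. Lists taken by symbol prefix hold families of near-identical genes (msp, his, col), whose members can share signal on an array.

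The test was tried on simulated arrays with the real number of rows and the fitted variances. It recovered 100% of 66 genes changed by 2 log2 units, 88.1% of 67 changed by 1 and 4.48% of 67 changed by 0.5. Of 19100 unchanged genes among the 19300 simulated, it called 6. In the data 43.9% of rows were called, so the adjusted threshold there admits larger unadjusted p-values. The simulated recovery of small changes therefore does not carry over to the data. In 100 simulated rounds, camera gave an unadjusted p under 0.05 for 5 unshifted lists of 40 genes and for 100 lists shifted by 0.5. Genes were simulated as independent, so these rates do not cover lists whose members correlate. In the data, the median estimated correlation of the 10 lists called with the preset correlation was 0.281. Alternatives covered centring, quantile and scale normalization, missing values, averaging of features, the variance model, array weights, the list test and leaving out each preparation.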

Results

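Adult hermaphrodites of C. elegans carrying embryos (TP10) were compared with a wild-type mixed reference on 3 arrays, each holding RNA of 1 preparation in one channel and the reference in the other. Arrays 1, 2 and 3 held 19864, 19855 and 19854 log2 ratios. Across 19300 genes and unnamed features, the log2 ratios correlated with Pearson's r of 0.862 between arrays 1 and 2, 0.850 between arrays 1 and 3, and 0.898 between arrays 2 and 3. These correlations run across genes, which are not independent replicates. The ratios were spread more widely on array 1 (SD 0.888 log2) and array 2 (SD 0.848) than on array 3 (SD 0.674). The median SD of a gene between the arrays was 0.232. Higher and lower refer to TP10 relative to the reference, a direction that is likely but not settled by a stated dye. Because each array was centred on its median, both words are also relative to the median gene or feature. A shift common to most genes would not be seen.

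The design asks which transcripts of the embryo-bearing adult are more or less abundant than in the mixed reference. At an adjusted p under 0.05 (limma), 8476 of 19300 genes and unnamed features differed, 4246 higher and 4230 lower. Of these, 3202 differed by at least 2-fold, 1600 higher and 1602 lower. Centring puts equal numbers of ratios above and below 0 on each array, so the near balance of these counts is not a finding. Among genes with a symbol, past the threshold and of 1 sign on all arrays, the highest included irg-5 and irg-8, named as infection response genes, at 4.07 ± 1.24 and 2.96 ± 0.16 log2 (SD, n = 3). With them stood pud-2.1 at 3.69 ± 0.84, pud-4 at 2.81 ± 0.94, the cuticle collagens col-101 at 3.51 ± 0.51 and col-143 at 3.00 ± 0.20, the glucosyltransferase family gene ugt-22 at 3.29 ± 0.78 and the cytochrome P450 gene cyp-35C1 at 2.87 ± 0.60. All 8 had an adjusted p of 3.83e-05 or less. The lowest of such genes was adh-1, an alcohol dehydrogenase gene, at -5.65 ± 0.30, or 50.0-fold lower. It was followed by the C-type lectin gene clec-60 at -5.07 ± 0.34, the acyl-CoA synthetase gene acs-2 at -4.93 ± 0.32, the collagen genes col-36 at -4.84 ± 0.33 and rol-8 at -4.46 ± 0.35, scl-2 at -4.44 ± 0.15, the fatty acid desaturase gene fat-3 at -4.31 ± 0.33 and the small heat shock gene hsp-12.6 at -4.30 ± 0.73. Their adjusted p was 1.71e-06 or less.

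These calls rest on limma's sharing of variance across genes. An unmoderated one-sample test with 2 residual degrees of freedom left 1 gene past the threshold, unk-1, which was named after its value was seen, although 6829 genes and features had an unadjusted p under 0.05. Leaving out 1 preparation gave between 6754 and 7796 calls.

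**Figure D1:**
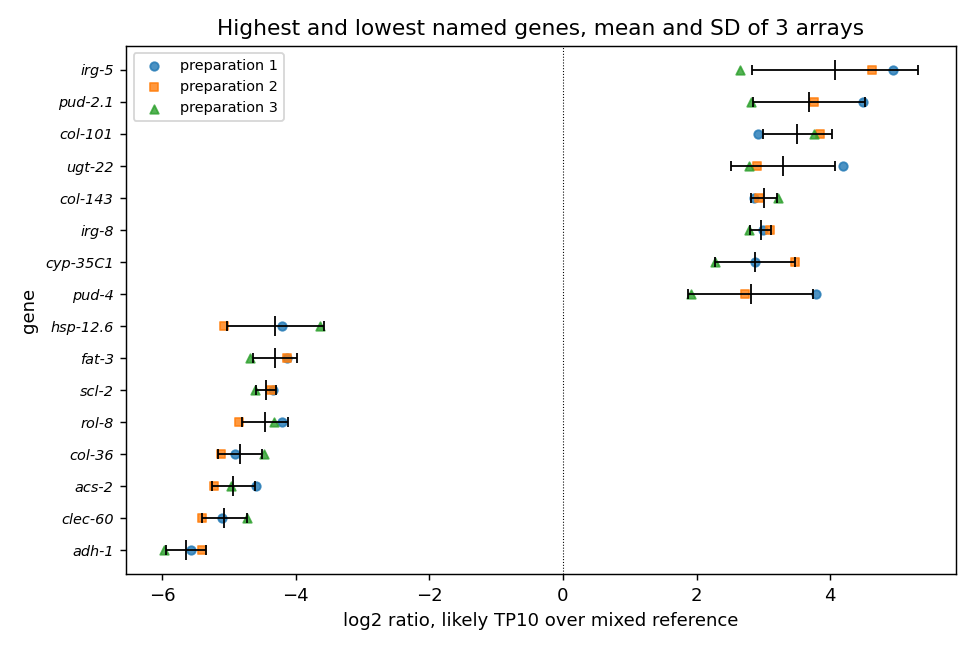
Log2 ratio (horizontal axis) of the 8 highest and 8 lowest named genes, with a symbol for each of the 3 preparations and the mean ± SD as a tick with bars. On every array all 8 of the first set lie above 0 and all 8 of the second set below it, from 4.07 for irg-5 to -5.65 for adh-1.

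Genes of oogenesis, the germ line and dividing cells were higher in TP10. All 24 measured oocyte and maternal embryonic regulators were higher, with a median of 1.69 log2 (3.23-fold). They included the Pumilio-family RNA-binding genes puf-6 at 2.55 ± 0.53 and puf-7 at 2.45 ± 0.21, and rme-2, the yolk receptor of oocytes, at 2.51 ± 0.37 (SD, n = 3). Of 40 germ line and meiosis genes 38 were higher and none lower, with a median of 1.23. The germ-granule RNA helicase genes glh-2 and glh-1 stood at 2.74 ± 0.42 and 2.73 ± 0.16, and cgh-1, a germline RNA helicase gene, at 2.57 ± 0.55. Of 46 DNA replication and cell cycle genes 40 were higher and none lower, with a median of 1.29. The kinesin gene klp-7 stood at 2.36 ± 0.42, the B-type cyclin gene cyb-3 at 2.06 ± 0.35 and the replicative helicase subunit mcm-2 at 1.98 ± 0.24. Adjusted over the list alone, 24, 40 and 40 members of these lists passed, all higher.

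Each of the 3 lists differed from the other genes with the preset correlation (camera, adjusted p = 1.32e-13 for oocyte regulators, 1.25e-16 for germ line and 3.13e-15 for cell cycle). The call was lost for each with a correlation estimated from the 3 arrays, at an adjusted p = 0.366. On the 2 degrees of freedom of that test, none of the 3 lists passed even with a correlation of 0 (adjusted p = 0.0524 for each).

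Eggshell and egg activation genes were also higher, 11 of 14, with a median of 0.99 log2. The eggshell genes cbd-1 and cpg-1 stood at 2.57 ± 0.58 and 2.40 ± 0.49, and egg-4 at 1.90 ± 0.20 (SD, n = 3). The 1 lower member was spe-11, which encodes a factor supplied by sperm, at -0.80 ± 0.45 (chosen after its value was seen). The counts adjusted over the list alone were 11 higher and 1 lower. The list passed with an adjusted p of 3.80e-05 and not with an estimated correlation (adjusted p = 0.366). Of the yolk proteins 3 of 6 genes were measured, too few for the list test. vit-2 was higher at 1.00 ± 0.27, with an adjusted p of 4.85e-04. vit-6 stood at 0.41 ± 0.42 and vit-5 at 0.27 ± 0.23, neither past the threshold (adjusted p = 0.0842 and 0.174). Leaving out 1 preparation gave 0.17 to 0.56 for vit-6 and 0.14 to 0.34 for vit-5. Adjusted over the list alone, 1 yolk protein gene again passed.

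Sperm genes were lower. Of 78 measured, 44 were lower, 3 higher and 31 not past the threshold, with a median of -0.59 log2. The major sperm protein genes msp-59, msp-51 and msp-33, which belong to a family of near-identical copies, stood at -2.19 ± 0.42, -2.18 ± 0.25 and -2.08 ± 0.38 (SD, n = 3). The 3 higher members, chosen after their values were seen, were spe-41 at 0.87 ± 0.26, spe-44 at 0.81 ± 0.32 and spe-4 at 0.44 ± 0.14. There were 47 lower and 4 higher genes adjusted over the list alone. The list passed with an adjusted p of 2.49e-08 and not with an estimated correlation (adjusted p = 0.366). Of 14 genes of the male tail and male neurons, 2 were lower and none higher. They were the neuropeptide gene nlp-8 at -3.28 ± 0.52, which is also in the neuronal list, and cwp-4 at -0.47 ± 0.17. The cwp-4 call ended without preparation 1 (adjusted p = 0.0680) or preparation 3 (adjusted p = 0.115), and adjusted over the list alone 1 gene passed. The list did not differ from other genes (adjusted p = 0.828), and its median of 0.09 and mean of -0.20 had opposite signs.

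Cuticle collagens went both ways. Of 152 measured, 77 were lower, 31 higher and 44 not past the threshold, with a median of -0.48 log2 and an SD between members of 1.54. The lowest were col-36, rol-8 and col-2, the last at -3.93 ± 0.32 (SD, n = 3), while col-101 and col-143 were among the 8 highest genes that the naming rule admits. The list as a whole was lower than other genes (adjusted p = 1.46e-04), but not with an estimated correlation (adjusted p = 0.667). Molting genes were lower in 20 of 36 cases and higher in 3, with a median of -0.53. The cuticlin gene cut-1 stood at -2.35 ± 0.95, mlt-10 at -1.89 ± 0.46 and the hedgehog-related gene wrt-10 at -1.58 ± 0.68. The 3 higher members, chosen after their values were seen, were nhr-23 at 1.06 ± 0.39, bli-4 at 0.62 ± 0.12 and ptr-18 at 0.51 ± 0.35. The list passed with an adjusted p of 3.80e-05, and not with an estimated correlation (adjusted p = 0.531). In fry, which tests the members against no change and not against other genes, the adjusted p was 0.0781 for collagens and 0.0855 for molting genes. Adjusted over the list alone, 77 collagens were lower and 32 higher, and 21 molting genes were lower and 3 higher.

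Of 19 genes of dauer larvae and starved first-stage larvae, 10 were lower and 2 higher, with a median of -0.42 log2. hsp-12.6 stood at -4.30 ± 0.73, dod-3 at -3.07 ± 0.50 and cut-1, shared with the molting list, at -2.35 ± 0.95 (SD, n = 3). The 2 higher members were sip-1 at 1.03 ± 0.43 and daf-15 at 0.77 ± 0.16, chosen after their values were seen. The counts adjusted over the list alone were again 10 and 2. The list passed with an adjusted p of 0.0110 and not with an estimated correlation (adjusted p = 0.366).

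Among differentiated tissues, neuronal genes were lower. Of 147 measured, 97 were lower, 3 higher and 47 not past the threshold, with a median of -0.81 log2 (1.76-fold). The neuropeptide genes flp-1, nlp-8 and nlp-80 stood at -3.45 ± 0.42, -3.28 ± 0.52 and -3.28 ± 0.18 (SD, n = 3). The 3 higher genes were tdc-1 at 0.96 ± 0.13 and tbh-1 at 0.51 ± 0.17, which encode the enzymes of tyramine and octopamine synthesis, and unc-11 at 0.67 ± 0.16. All 3 were chosen after their values were seen. Adjusted over the list alone, 101 were lower and 3 higher. The list passed with an adjusted p of 1.95e-16 and not with an estimated correlation (adjusted p = 0.366).

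Muscle, intestine and pharynx genes went both ways. Of 35 muscle genes 8 were higher and 6 lower, with a median of -0.05 log2. The troponin C gene tnc-2 stood at -2.92 ± 0.44, the troponin T gene tnt-2 at 1.17 ± 0.56 and the perlecan gene unc-52 at 1.00 ± 0.29 (SD, n = 3). Of 46 intestine genes 15 were higher and 17 lower, with a median of -0.04. The metallothionein gene mtl-1 stood at -2.66 ± 0.17, the ferritin gene ftn-1 at -2.20 ± 0.34 and the acyl-CoA dehydrogenase gene acdh-1 at 2.64 ± 0.74. Of 70 pharynx genes 13 were higher and 29 lower, with a median of -0.16. Beside tnc-2, phat-5 stood at -1.97 ± 0.49 and pqn-35 at -1.93 ± 0.26. None of the 3 lists passed (adjusted p = 0.828, 0.820 and 0.0576), but pharynx passed without preparation 3 (adjusted p = 0.0443). In fry, which tests members against no change, the adjusted p was 0.589, 0.241 and 0.0474 in the same order. With an estimated correlation it was 0.930, 0.914 and 0.366. Tests adjusted over the list alone passed 14 muscle, 32 intestine and 44 pharynx genes.

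**Figure D2:**
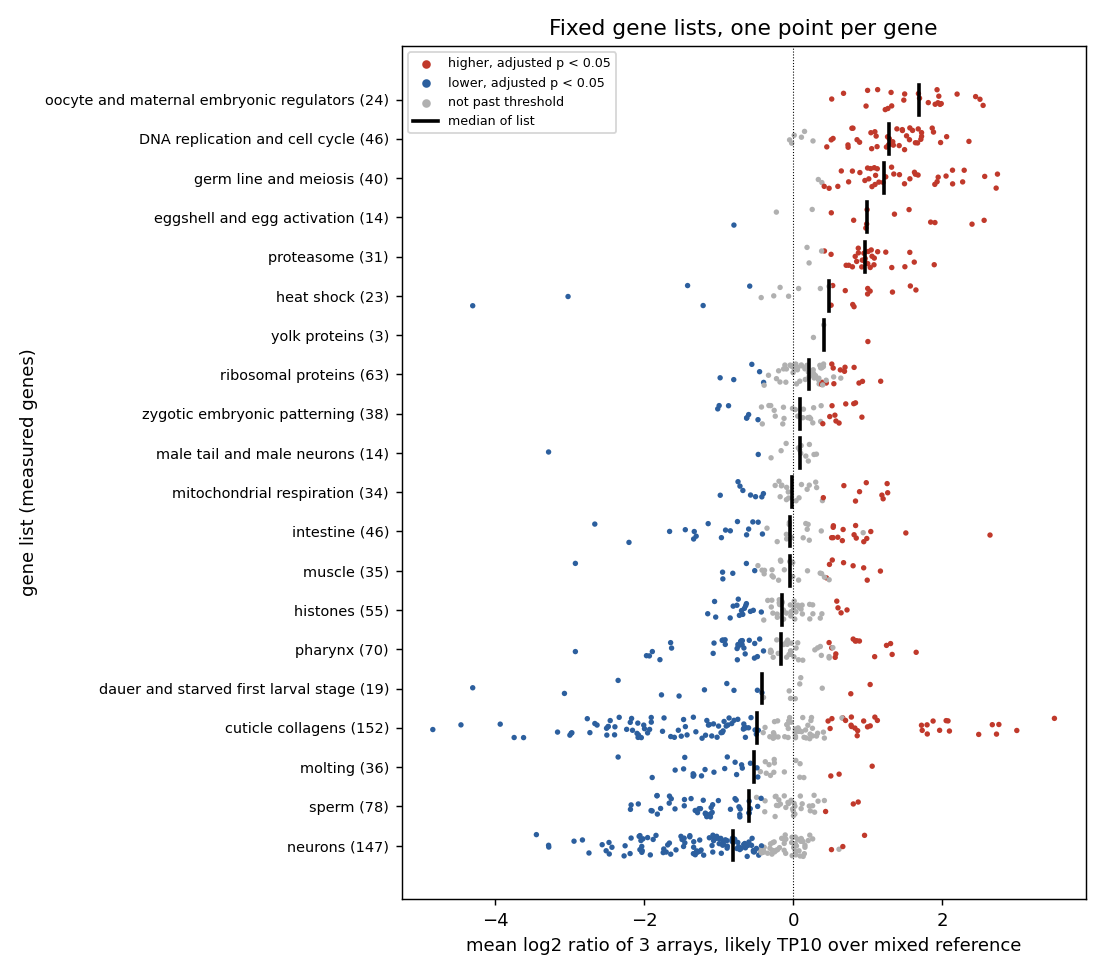
Mean log2 ratio over 3 arrays (horizontal axis) of each measured gene in the 20 fixed lists, sorted by median, with 1 point per gene coloured by its limma call and a black bar at the list median. Medians run from 1.69 for oocyte and maternal embryonic regulators to -0.81 for neurons, and cuticle collagens span both sides of 0.

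Among genes used by most cells, proteasome subunits were higher. Of 31 measured, 28 were higher and none lower, with a median of 0.96 log2 (1.95-fold). They included rpn-1 at 1.89 ± 0.27, rpt-2 at 1.63 ± 0.41 and rpn-2 at 1.57 ± 0.25 (SD, n = 3). The list passed with an adjusted p of 3.67e-11 and not with an estimated correlation (adjusted p = 0.366), and 29 members passed adjusted over the list alone. Of 23 heat shock genes 11 were higher and 5 lower, with a median of 0.48 and a mean of 0.02. The small heat shock genes hsp-12.6 and hsp-12.3 were lower at -4.30 ± 0.73 and -3.02 ± 0.52, and hsp-110 was higher at 1.65 ± 0.24. The other 3 lower genes, chosen after their values were seen, were hsp-16.20 at -1.42 ± 0.50, hsp-70 at -1.21 ± 0.10 and hsp-12.2 at -0.58 ± 0.20. The heat shock list did not differ from other genes (adjusted p = 0.324), and 17 members passed adjusted over the list alone.

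Ribosomal protein genes were higher in 13 of 63 cases and lower in 5, with a median of 0.21 log2. rpl-11.1 stood at 1.18 ± 0.24, rpl-4 at 0.93 ± 0.14 and rpl-23A.1 at -0.98 ± 0.21 (SD, n = 3). The other 4 lower genes, chosen after their values were seen, were rpl-11.2 at -0.80 ± 0.22, rpl-38 at -0.55 ± 0.02, rpl-36A at -0.45 ± 0.29 and rps-17 at -0.40 ± 0.14. Histone genes, many of them near-identical copies, were lower in 16 of 55 cases and higher in 4, with a median of -0.15. his-71, his-10 and his-1 stood at -1.15 ± 0.25, -1.06 ± 0.46 and -1.04 ± 0.10. The 4 higher genes, chosen after their values were seen, were his-47 at 0.72 ± 0.12, his-68 at 0.64 ± 0.26, his-74 at 0.60 ± 0.29 and his-24 at 0.59 ± 0.56. Neither list passed (adjusted p = 0.0576 for both). Ribosomal proteins passed without preparation 3 (adjusted p = 0.0224) and on ranks (adjusted p = 0.0347). Histones passed without preparation 1 (adjusted p = 0.00855), on ranks (adjusted p = 0.0368) and after scaling the arrays to one spread, an alternative chosen after seeing the data (adjusted p = 0.0463). In fry the adjusted p was 0.214 for ribosomal proteins and 0.163 for histones, and with an estimated correlation 0.800 and 0.750. Of ribosomal protein genes 12 passed adjusted over the list alone, and of histone genes 20.

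Mitochondrial respiration genes were higher in 9 of 34 cases and lower in 8, with a median of -0.01 log2 and a mean of 0.12. sdha-2 stood at 1.27 ± 0.12, ucr-2.3 at 1.26 ± 0.22 and asb-1 at 1.21 ± 0.10 (SD, n = 3). Zygotic embryonic patterning genes were higher in 10 of 38 cases and lower in 7, with a median of 0.10. The homeobox genes nob-1 and pal-1 stood at -1.01 ± 0.35 and 0.92 ± 0.08, and the GATA factor gene elt-3 at -0.99 ± 0.23. Neither list differed from other genes (adjusted p = 0.717 and 0.827), and 17 members of each passed adjusted over the list alone.

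Genes on the X chromosome had lower ratios than genes on the other chromosomes. Of 2256 X-linked genes, 229 (10.2%) were higher and 636 (28.2%) lower, against 3111 (24.3%) and 2939 (22.99%) of 12784 autosomal genes. Among autosomes the share of higher genes ran from 14.1% on chromosome V to 35.3% on chromosome III. Chromosome V was the autosome closest to X, with 25.3% of its genes lower and a median of -0.08 log2. The median was -0.12 on X and 0.01 on the autosomes together. X-linked genes were lower than other genes with the preset correlation (camera, p = 0.00357) and on ranks (camera, p = 0.00215). With an estimated correlation the call was lost (camera, p = 0.0904). The estimate of 0.0088 lay below the preset 0.01, so the loss came with the fewer degrees of freedom and not with the correlation. In fry, which tests against no change, p was 0.0125.

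**Figure D3:**
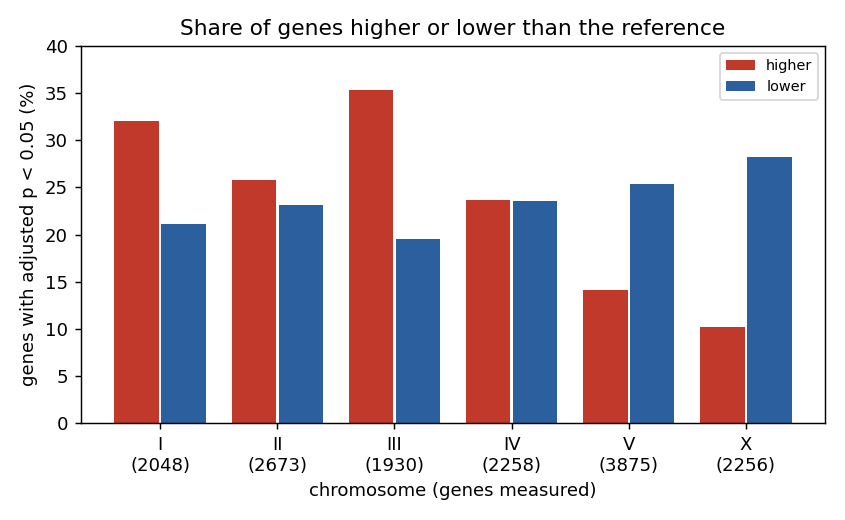
Percentage of measured genes that were higher or lower than the reference at an adjusted p under 0.05 (vertical axis) on each chromosome, with the number of genes below each name. The X chromosome has the smallest share of higher genes, 10.2%, and chromosome III the largest, 35.3%.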

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

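The number of genes differing from the reference (8476) lay between 8425 and 9193 with the values as deposited, centred on the mean, quantile-normalized, scaled, with values on at least 2 arrays, without the tenth of genes of highest SD, with features kept apart, with robust eBayes and with array weights. Genes called in both the main test and any of these alternatives had 0 changes of direction, which was not counted for features kept apart. The deposited values were already centred, so none of these settings could show a shift common to most genes. Without 1 preparation the count was 6754 to 7796 (3490 to 3962 higher, 3264 to 3834 lower), and the count at least 2-fold was 2941 to 3804 (1446 to 1941 higher, 1495 to 1863 lower). The unmoderated one-sample test called 1 gene, 0 higher and 1 lower, also 1 at 2-fold with 0 higher and 1 lower, while 3379 higher and 3450 lower had an unadjusted p under 0.05. It has 2 residual degrees of freedom per gene. Of 19 gene lists 10 passed, 12 on ranks, 10 to 12 without 1 preparation, and 0 with an estimated correlation. In settings chosen after seeing the data, 11 passed after scaling to one spread, and 0 after that scaling combined with an estimated correlation. Against no change, which is another question, 9 lists passed by fry. The muscle list reversed without preparation 2 (adjusted p = 0.796, range 0.541 to 0.927 over the preparations left out) and the intestine list without preparation 3 (adjusted p = 0.875, range 0.418 to 0.875), and neither was past the threshold in any setting run. The p for X-linked genes was 0.000992 to 0.0178 without 1 preparation, 0.0904 with an estimated correlation and 0.260 with that and scaling, a setting chosen after seeing the data. Spearman's rho between arrays 1 and 2, 1 and 3, and 2 and 3 was 0.799, 0.795 and 0.847, and without the remaining preparation Pearson's r was 0.860, 0.847 and 0.894. Of 68 named genes, cwp-4 alone lost its call in a leave-one-out setting, and 0 lost it with the values as deposited or quantile-normalized, or in the settings chosen after seeing the data, centring on the mean and scaling. No paired analysis was possible because there is a single group of samples. With 1 group, no splits of samples between groups exist. Detection limits are unknown because signal over background was not used here.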

Other observations

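Of the tests in this section, the comparison of neuronal with muscle and intestine genes and the symbol classes were chosen after the main results were seen; the other predictions were written before their own test was run. Genes outside the fixed lists were grouped by the prefix of their symbol, which can stand for a gene family or, as in let, unc or lin, for a phenotype. Of the 88 prefixes with at least 15 measured genes, 32 differed from other genes (camera, preset correlation, adjusted over the prefixes), 11 higher and 21 lower, let among the higher. None passed with an estimated correlation, where the smallest adjusted p was 0.574, on the same 2 degrees of freedom that ended the list calls. Nucleoporin genes (npp) were higher in 20 of 21 cases, with a median of 1.196 log2, and npp-9, chosen after its value was seen, stood at 2.32 ± 0.30 (SD, n = 3). Translation initiation factors (eif) were higher in 13 of 19 cases with a median of 0.84, and DnaJ chaperones (dnj) in 13 of 23 with a median of 0.54. Transthyretin-related genes (ttr) were lower in 27 of 45 cases and higher in 2, with a median of -0.65. The pals genes were lower in 13 of 24 cases and higher in 1, and nuclear hormone receptors (nhr) lower in 83 of 233 and higher in 5. In the chemoreceptor families, of 174 srh genes 8 were lower and 3 higher, and of 166 str genes 7 were lower and 2 higher.

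Several paralogs of one complex stood on opposite sides of the reference. rpl-11.1 was at 1.18 ± 0.24 and rpl-11.2 at -0.80 ± 0.22 log2, rpl-23A.2 at 0.88 ± 0.29 and rpl-23A.1 at -0.98 ± 0.21, and ucr-2.3 at 1.26 ± 0.22 and ucr-2.1 at -0.71 ± 0.32 (SD, n = 3). All 6 passed the limma threshold, and these pairs were picked after their values were seen.

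All 10 list calls ended with an estimated correlation. The explanation tested was that this test has only the degrees of freedom of 3 arrays, which are 2. With the preset correlation kept and the p taken on those degrees of freedom, 0 of the 10 lists passed. With a correlation of 0, also 0 passed, the smallest adjusted p being 0.0524. These degrees of freedom alone were thus enough to end all 10 calls, but correlation within lists is a further limit. The correlations estimated for these lists from 3 arrays ran from 0.00848 (dauer) to 0.675 (oocyte regulators), against the preset 0.01. For collagens the adjusted p (camera) was 0.122 with the preset correlation on these degrees of freedom and 0.667 with the estimate. The preset p-values may thus also be too small for lists whose members correlate. Whether the unequal spread of the arrays added to the loss stays open: 0 lists passed again after scaling, but with a correlation of 0 the scaled arrays also gave 0 lists (smallest adjusted p = 0.0540), so this test could not have come out otherwise.

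Among the 8 lowest genes of the naming rule was acs-2 at -4.93 ± 0.32 log2 (SD, n = 3), known to be induced by fasting, as is fil-1 at -3.70 ± 0.27, which lies outside the rule and was chosen after its value was seen. As a hypothesis, the animals of the reference may have had less food than the TP10 animals. Of 9 other measured genes of a fasting-raised list written before their values were seen, 7 were lower and 0 higher, with a median of -1.32 (95% bootstrap interval -1.88 to -0.25). Against it, of the genes known to be lowered by fasting, also listed before their values were seen, fat-7 was lower in TP10 at -1.45 ± 0.06, and fat-5 stood at -0.21 ± 0.20, so the hypothesis stays open. Dye bias of single probes cannot be told apart, since the labels name 0 arrays with exchanged dyes, and a stage difference was not tested.

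Neuronal genes had a median of -0.81 log2 while muscle and intestine genes together had -0.05. Whether RNA of the germ line and embryos diluted all somatic RNA alike stays open. The medians differed by -0.77 (95% bootstrap interval -1.10 to -0.54), and the prediction, written after the pattern was seen, would have counted an interval below 0 against dilution. That interval bounds the medians and not the genes, which went both ways with an SD of 0.894 between the muscle and intestine genes. The requirement that the gap exceed this SD was added after the gap was known; with it the test decides nothing, and the gap is also the pattern itself. The interval of the median of neuronal genes was -0.99 to -0.64, which the prediction would count against noise scattered at random around no change. It rests on the same genes that formed the pattern, so it restates the pattern and decides nothing about noise. The median of these genes was -0.89, -0.90 and -0.62 on arrays 1, 2 and 3, so the shift repeated between arrays. The median SD between arrays of neuronal genes was 1.00 times that of all other genes. Spot intensities were not used, so this ratio cannot show whether neuronal spots were weak. A bias of weak spots common to the arrays stays open, because it would not be part of the SD between arrays. A difference in stage between the TP10 adults and the reference also stays open, as a biological explanation that was not tested.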
